A study of Homo sapiens with 4 samples.

How the data were processed

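RNA-seq was measured in 4 libraries of HUES8, a human embryonic stem cell line kept undifferentiated on a Matrigel coating in mTeSR1 medium. Per the labels, 2 libraries carry the genotype WT and 2 the genotype CPT2 KO, and total RNA was extracted before library preparation. Per the submitters' processing notes, the tools were HISAT2 2.1.0, a spliced aligner, and featureCounts 1.6.4, a read counter, with the genome build hg38 (GRCh38). The deposited table holds raw read counts per gene symbol, not normalized, with gene lengths, per the file headers. Whether the kit and the counting used strand, how reads with several alignments were treated and which annotation release was counted are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore be assigned to either partner, and this is said of the called genes named in the results whose exons overlap another gene.

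The table listed 59050 genes, of which 31279 had a count in at least 1 library. Genes with too few counts for a test were removed with filterByExpr of edgeR by group, leaving 17564. Library totals ranged from 16887789 to 20460031 counts, so 1 count was worth 0.0485 to 0.0603 CPM. CPM, counts scaled to a common library size, were computed from the deposited counts with library sizes scaled by the trimmed mean of M values (TMM). Differences between the groups were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust estimation, group as the only term and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. This is the main fit, and results are from it unless an alternative is named. Log2 fold changes are the libraries labelled CPT2 KO over those labelled WT, and the standard error (SE) of each was taken from its size divided by the square root of F. A fold against a group at 0 in both libraries was set against a floor of 3 counts per library. Counting intervals are exact binomial intervals at 95% and cover counting error only.

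A set of 31 gene lists was fixed before the data were examined, as were the design, the rule for naming genes and all but 1 of the alternatives. The alternative added after seeing the data removes a trend on gene length and GC content. Lists can share genes, such as ACLY in fatty acid synthesis and acetylation, SLC2A3 in hypoxia and glycolysis and NODAL in mesendoderm and Nodal/Activin. Calls in lists that share genes are therefore not separate. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a common direction, were run beside it. Counts of called members are given over all tested genes and adjusted over the list alone, the latter where it is above 0, except for 1 list where it is not reported here. The genes named are 12 fixed genes, up to 10 with the largest change in each direction among called genes with at least 5 CPM and no overlap between the groups, and up to 4 members of each list. WNT3, EOMES, CER1, MIXL1, GATA4, GATA6, ESRRB, EVX1, NPFFR2, BNIP3, SOX3, HOXD9, HOXB3, TDGF1 and PAX6 fall outside that rule and were chosen after their values were seen, as were members named only as called over their list alone and genes named only in the closing observations.

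Gene positions come from GENCODE 29 on GRCh38, matched by symbol. Of the 59050 symbols, 56378 were found there and 56159 had a single position. Symbols without a row in the table, such as SIRT6, were not analysed here, and some called genes are not reported here.

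The fit was tested on simulated data drawn from the means and library sizes of the 4 libraries, with 200 changed genes in each of 5 runs and a median of 17116 genes tested. At changes of 1.5-fold, 2-fold and 4-fold, edgeR recovered 10.8%, 54.7% and 84.7% of the changed genes, and 5.52% of its calls were false. Each gene was drawn at the fitted dispersion trend, and no library was made to stand apart. Recovery and false calls in the 4 libraries may therefore differ from these. The cholesterol synthesis list, shifted by 1.5-fold, was called in 5 of 5 runs with the preset correlation and in 0 of 5 with the estimated correlation. The preset correlation called 1 other list in all runs together. Genes were drawn independently, so these runs cannot show how the preset performs where members of a list vary together. In the 4 libraries the estimated correlation was 0.94 for this list. It ranged from -0.081 (BMP targets) to 0.98 (mitochondrially encoded oxidative phosphorylation), on 2 residual degrees of freedom. Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood estimate, the replicate number as a block, each library left out in turn, mitochondrial genes left out, a threshold of 0.01 and a test against a 1.5-fold change.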

Results

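Gene expression was compared between 2 libraries of HUES8 human embryonic stem cells labelled WT and 2 labelled CPT2 KO. CPT2, carnitine palmitoyltransferase 2, releases long-chain acyl groups from carnitine inside mitochondria and so feeds fatty acid oxidation. By its title the study concerns fatty acid metabolism and SMAD3 acetylation in the formation of definitive endoderm, and the comparison asks how stem cell transcripts differ with the CPT2 genotype. The libraries labelled WT held 18356754 and 20460031 counts and those labelled CPT2 KO held 20219396 and 16887789. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 43.8 for the pair labelled WT and 11.3 for the pair labelled CPT2 KO. Against the libraries labelled CPT2 KO it was 50.9 and 58.3 for replicate 1 labelled WT and 13.5 and 13.7 for replicate 2. By this measure replicate 1 labelled WT stood apart from the other 3 libraries. The correlation of log2 CPM of replicate 2 labelled WT was 0.979 with replicate 1 and 0.978 and 0.977 with those labelled CPT2 KO.

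The CPT2 transcript ran against the labels. CPT2 had 52 and 72 counts in the libraries labelled WT and 233 and 170 in the libraries labelled CPT2 KO, or 3.16 ± 0.478 CPM against 10.9 ± 0.912 CPM (SD, n = 2 each). It was 3.44-fold higher in the libraries labelled CPT2 KO (log2 fold change 1.78, SE 0.27, edgeR adjusted p = 0.0218). The gene lies on chromosome 1 at 53196429 to 53214197 (GRCh38, plus strand, protein coding), and its exons overlap AL606760.2 and CZIB (listed as C1orf123 in GENCODE 29) on the opposite strand. CZIB had a log2 fold change of -0.12 (edgeR adjusted p = 0.863), and AL606760.2 had 2 counts in 1 library and 0 in the others. The CPT2 call was lost without replicate 1 (edgeR adjusted p = 0.168) or replicate 2 (0.0511) of the group labelled CPT2 KO. Because of this direction, every difference below is stated between libraries as labelled.

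**Figure D1:**
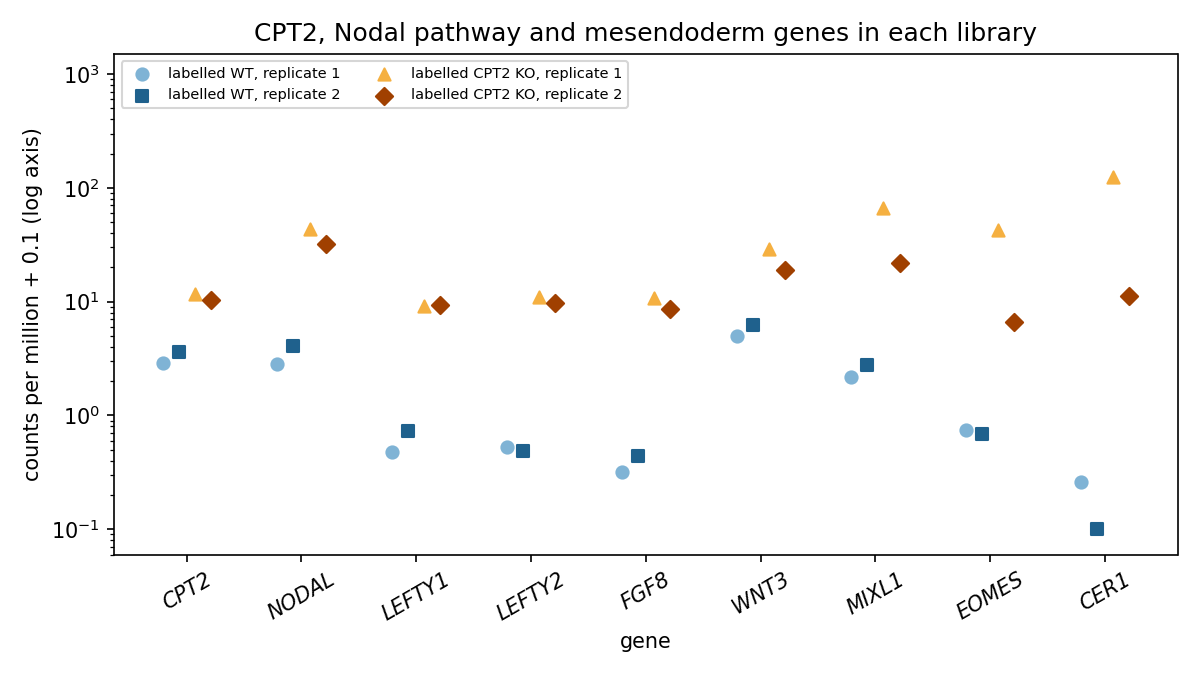
CPM plus 0.1 on a log axis for 9 genes, with 1 point for each of the 4 libraries. CPT2, NODAL, LEFTY1, LEFTY2, FGF8 and WNT3 lie close together in both libraries labelled CPT2 KO and above both labelled WT, whereas EOMES and CER1 differ widely between the libraries labelled CPT2 KO.

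NODAL and its antagonists LEFTY1 and LEFTY2 were higher in the libraries labelled CPT2 KO. NODAL, the ligand that patterns the primitive streak, rose from 3.35 ± 0.898 to 37.7 ± 8.37 CPM (SD, n = 2 each; log2 fold change 3.49, SE 0.26, edgeR adjusted p = 0.000416). LEFTY1 and LEFTY2 rose by 4.15 and 4.63 on the log2 scale (edgeR adjusted p = 0.00114 and 0.000841). LEFTY1 and LEFTY2 are close paralogues and share exon positions with AL117348.2 and AL117348.1, and NODAL overlaps AC022532.1 on the opposite strand, so the assignment of their reads is uncertain. Of 27 tested members of the Nodal/Activin list, 4 were higher and 0 lower, and 8 were higher when adjusted over the list alone. Over all tested genes, 7 of the 27 were called with DESeq2 and 8 without replicate 2 labelled WT. The log2 fold change was positive for 21 members and negative for 6. The list median was 0.28 (camera adjusted p = 5.5e-14, and adjusted p = 0.389 with an estimated correlation), and it was 0.16 without replicate 2 labelled WT and 0.12 without replicate 2 labelled CPT2 KO. TDGF1, the Nodal co-receptor, had a log2 fold change of 0.47 (edgeR adjusted p = 0.229). SMAD2 and SMAD3, which carry the signal to the nucleus, had log2 fold changes of 0.023 and 0.30 (edgeR adjusted p = 0.973 and 0.569).

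Among 12 tested mesendoderm markers, 3 were called higher, FGF8 (log2 fold change 5.06, SE 0.44, edgeR adjusted p = 0.000841), NODAL and WNT3 (2.13, SE 0.26, edgeR adjusted p = 0.00646), and 0 lower, and the other 9 did not pass. Adjusted over the list alone, 6 were higher and 1, EVX1, was lower. The list median was 3.52 (camera adjusted p = 3.0e-21, and adjusted p = 0.699 with an estimated correlation). EOMES stood at 0.650 and 0.582 CPM in the libraries labelled WT and at 42.9 and 6.57 CPM in replicates 1 and 2 labelled CPT2 KO, and was not called (edgeR adjusted p = 0.569). CER1 stood at 0.163 and 0 CPM against 124 and 11.1 CPM (edgeR adjusted p = 0.436), and MIXL1 at 2.06 and 2.67 against 66.7 and 21.7 CPM (0.344). EOMES, CER1 and MIXL1 were called with DESeq2, and the list had 8 called members with it. Leaving out 1 library labelled CPT2 KO removes the difference between the 2 from the fit, so calls made that way do not bear on it. The list median was 2.49 without replicate 1 and 4.01 without replicate 2 of that group. The WNT3 call was lost without replicate 1 of the group labelled CPT2 KO.

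Definitive endoderm markers gave 0 calls among 10 tested in edgeR, with GATA4 called when adjusted over the list alone and in 8 of 14 alternatives over all genes, DESeq2 and each library labelled WT left out among them, and a median of 0.51 (camera adjusted p = 0.00216, and adjusted p = 0.699 with an estimated correlation). GATA4 had 5 and 4 counts in the libraries labelled WT and 113 and 30 in replicates 1 and 2 labelled CPT2 KO. It was not called with replicate 1 labelled CPT2 KO left out. SOX17 and GATA6, regulators of endoderm, were below the count filter, with 0 and 0 counts in the libraries labelled WT and 46 and 7 (SOX17) or 74 and 7 (GATA6) in those labelled CPT2 KO. The list lost its call without replicate 2 of the group labelled WT (median 0.44, camera adjusted p = 0.317), and its median was 1.57 without replicate 1 labelled WT and 0.23 without replicate 1 labelled CPT2 KO. The list had 2 called members, GATA4 and CER1, with DESeq2.

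Of 13 tested neuroectoderm markers, SIX6 and SOX1 fell in the libraries labelled CPT2 KO and 0 rose, and 3 were lower when adjusted over the list alone, SOX3 being the third. The log2 fold change was negative for 8 members and positive for 5, among them PAX6 (1.01, edgeR adjusted p = 0.664). SOX1, a marker of neural progenitors, fell by 3.30 on the log2 scale, from 5.38 ± 1.32 to 0.522 ± 0.312 CPM (SD, n = 2 each; edgeR adjusted p = 0.0164). SIX6, an eye field factor, went from 24 and 67 counts to 2 and 1 (edgeR adjusted p = 0.0382). The list median was -0.32 (camera adjusted p = 0.000746, and adjusted p = 0.699 with an estimated correlation), and it was -0.20 without replicate 1 and -0.16 without replicate 2 labelled WT. In the neural crest list (8 tested, median -0.14, camera adjusted p = 0.111), PAX7 fell by 2.43 on the log2 scale (edgeR adjusted p = 0.000934) and ETS1 rose by 1.34 (0.0112, lost without replicate 1 labelled CPT2 KO), and adjusted over the list alone 1 was higher and 2 were lower. SIX6 lost its call without either library labelled CPT2 KO, and SOX1 without replicate 2, while SOX3 was called with DESeq2 and without replicate 2 labelled WT.

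Core pluripotency genes gave 0 calls among 25 tested in edgeR (median 0.10, camera adjusted p = 0.228), while 4 were called higher without replicate 2 labelled WT and 1 each with DESeq2 and without replicate 1 labelled WT. POU5F1, NANOG and SOX2 had log2 fold changes of 0.18, 0.24 and 0.11 (edgeR adjusted p = 0.710, 0.652 and 0.813). Of 11 tested naive pluripotency genes, 2 were higher, ZFP42 (log2 fold change 0.98, edgeR adjusted p = 0.0164) and TBX3 (1.44, 0.0396), and 0 lower. Adjusted over the list alone, 2 were higher and 1, ESRRB, lower. The naive list median was 0.54 (camera adjusted p = 0.0442, and adjusted p = 0.699 with an estimated correlation). ZFP42, TBX3 and the list itself lost their calls when either library labelled CPT2 KO was left out, and the list also without replicate 2 labelled WT (camera adjusted p = 0.272), while its median was 0.35 without replicate 1 labelled WT.

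CPT2 was left out of the fatty acid oxidation list, and the main edgeR fit called no listed gene of fatty acid metabolism. Mitochondrial fatty acid oxidation had 0 calls among 33 tested genes in edgeR (median -0.0037, camera adjusted p = 0.586), with log2 fold changes of 0.19 for CPT1A and 0.024 for SLC25A20, the partners of CPT2 in the carnitine shuttle. Peroxisomal oxidation (22 tested, median -0.020, camera adjusted p = 0.447) and lipid droplet and PPAR target genes (25 tested, median 0.047, 0.586) had 0 calls each, with FABP5 and PLIN2 called when the latter list was adjusted over the list alone. Fatty acid synthesis had 0 calls among 29 tested genes (median -0.11, camera adjusted p = 0.111). FASN, ACACA and ACLY, which make fatty acids and their acetyl-CoA precursor, had log2 fold changes of -0.78, -0.38 and -0.52 (edgeR adjusted p = 0.512, 0.493 and 0.503). Acetyl-CoA supply, acetyltransferase and deacetylase genes had a median of -0.18 over 35 tested genes (camera adjusted p = 0.0113, and adjusted p = 0.699 with an estimated correlation), with 0 calls, and 1 lower, HDAC9, when adjusted over the list alone or with DESeq2. Without replicate 1 of the group labelled WT this list median was -0.053 (camera adjusted p = 0.199), and it also lost its call without replicate 2 labelled CPT2 KO (0.0723). Without replicate 2 labelled WT, that group was replicate 1 alone, the library that stood apart. Calls that these lists gained in that setting rest on it. The fatty acid synthesis median was then -0.22, and it was -0.059 without replicate 1 labelled WT. Over all alternatives the log2 fold changes ranged from -1.15 to -0.28 for FASN, -0.54 to -0.19 for ACACA and -0.82 to -0.14 for ACLY. For CPT1A the range was -0.11 to 0.59. FABP5 was called in 5 of 15 alternatives, DESeq2 and each library labelled WT left out among them.

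Hypoxia response, glycolysis and cholesterol synthesis lists were lower in the libraries labelled CPT2 KO, and replicate 1 of the group labelled WT decided these shifts. Over 24 hypoxia genes the median was -0.94 (camera adjusted p = 0.000746), over 24 glycolysis genes -0.66 (0.00196) and over 25 cholesterol genes -0.50 (2.8e-07), each with adjusted p = 0.699 with an estimated correlation and 0 called genes. BNIP3, a hypoxia-induced gene of mitochondrial turnover, had 10932 and 2382 counts in the libraries labelled WT and 4014 and 1773 in those labelled CPT2 KO. Without replicate 1 of the group labelled WT the medians were 0.10 (camera adjusted p = 0.231), 0.18 (0.0366) and -0.036 (0.199), and without replicate 2 of that group they were -1.56, -1.17 and -0.79, with 14, 19 and 16 genes called lower. The hypoxia and glycolysis lists also lost their calls without replicate 2 labelled CPT2 KO (camera adjusted p = 0.0635 and 0.0723). Mitochondrially encoded subunits of oxidative phosphorylation (13 tested, median 0.56, camera adjusted p = 1.2e-05) and nuclear-encoded ones (72 tested, median 0.24, 3.2e-06) were higher as lists, with 0 called genes and adjusted p = 0.699 with an estimated correlation for both. Without replicate 1 labelled WT their medians were 0.17 (camera adjusted p = 0.0231) and 0.13 (0.00831), the mitochondrially encoded median was 1.09 without replicate 2 labelled WT, where all 13 mitochondrially encoded and 10 nuclear-encoded genes were called higher, and the nuclear-encoded list lost its call without replicate 2 labelled CPT2 KO (0.157). Mitochondrial genes took 4.15% of the counts in replicate 1 labelled WT and 7.21%, 7.84% and 7.73% in the other libraries.

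**Figure D2:**
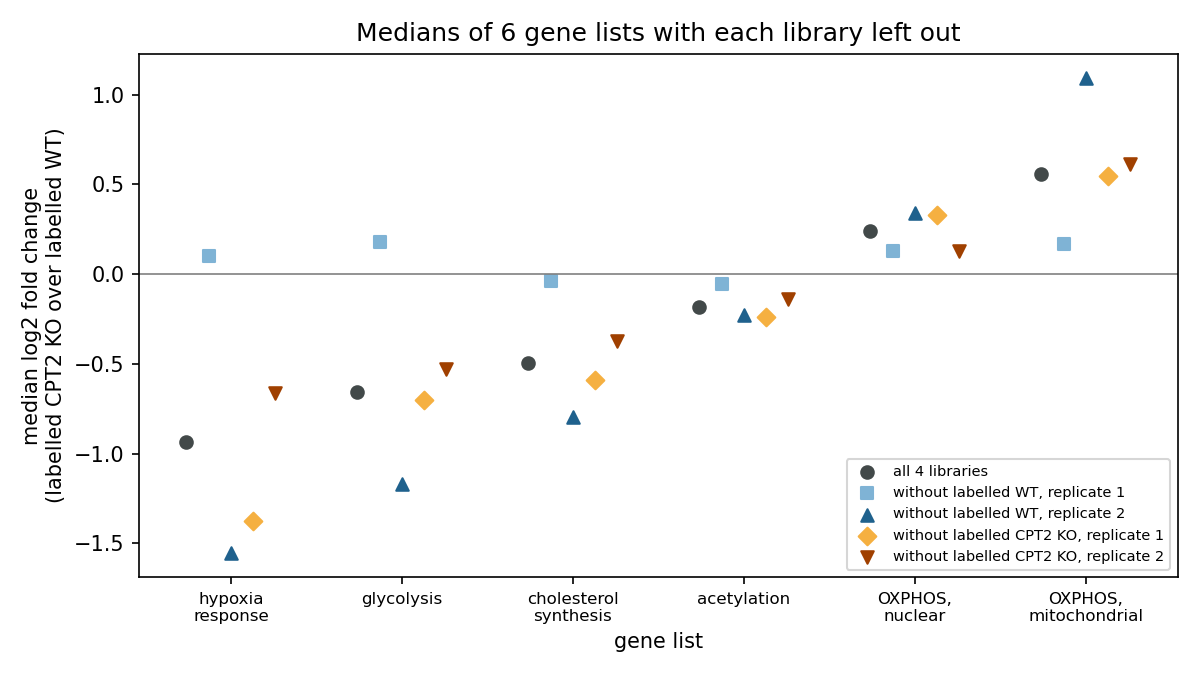
Median log2 fold change, libraries labelled CPT2 KO over those labelled WT, of 6 gene lists with all 4 libraries and with each library left out. The hypoxia median is -0.94 with all libraries and 0.10 without replicate 1 of the group labelled WT, and the glycolysis median goes from -0.66 to 0.18.

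Across all genes, edgeR called 63 higher and 10 lower in the libraries labelled CPT2 KO among 17564 tested, and 56 and 9 of these changed at least 2-fold. C9orf64 had 0 counts in both libraries labelled WT and 257 and 147 in those labelled CPT2 KO, at least 71.5-fold higher (edgeR adjusted p = 0.000926), and NPFFR2, a neuropeptide receptor gene, was at least 32.5-fold higher. ZNF37A, a zinc finger gene, had 2 and 3 counts against 193 and 181, a ratio of 79.4 (counting interval 33.7 to 246), and shares exon positions with AL117339.5, so its reads are uncertain. PCDHGC3 had 0 and 3 counts against 114 and 85, and shares exons with the other gamma protocadherins, so its reads are uncertain. The noncoding RNA LINC01108 rose from 6.15 ± 2.42 to 182 ± 34.6 CPM (SD, n = 2 each), and EBF2, LINC01508 and PHETA2 rose by 4.65, 4.18 and 4.16 on the log2 scale. Among the lower genes were HOXD10 and HOXC4 (log2 fold changes -1.94 and -1.72), C3, the central complement component (-1.66), SEMA6D (-1.48), C17orf51 (-1.34) and SORBS2 (-0.99). HOXC4 shares exons with HOXC5 and HOXC6, HOXD10 with HOXD11, C17orf51 with AC233702.6 and SORBS2 with AC104805.1, so their reads are uncertain too. PAX7 was the lower gene that kept its call with each library left out, and the other lower genes named here lost theirs without at least 1 library labelled CPT2 KO. Left out in turn, the libraries labelled CPT2 KO gave 31 higher and 2 lower calls without replicate 1 and 81 and 2 without replicate 2, and those labelled WT gave 113 and 36 without replicate 1 and 531 and 674 without replicate 2.

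In the main fit, the remaining lists had 0 calls over all tested genes in edgeR and were not called by camera. With no low count filter, camera called trophoblast and amnion (median 0.67). Their medians were -0.074 for mesoderm, 0.16 for trophoblast and amnion, 0.11 for fibroblast, -0.061 for endothelial and blood, 0.14 for BMP target, 0.036 for Wnt target, 0.058 for tricarboxylic acid cycle, -0.11 for integrated stress response, -0.046 for p53 target, 0.043 for cell cycle, 0.049 for immediate early and heat shock, -0.055 for epithelial to mesenchymal transition and -0.025 for imprinted genes. The endothelial and blood median, over 5 tested genes, ranged from -0.64 to 0.10 with each library left out. Adjusted over the list alone, the mesoderm list had 2 higher (PDGFRA and KDR) and 2 lower (FOXC1 and TBX5), BMP targets 2 higher (ID1 and BAMBI) and 1 lower (ID2) and fibroblast 1 higher (TAGLN). The count for trophoblast and amnion is not reported here, and the other lists of this group had 0. DESeq2 called ID1 and TAGLN higher and TBX5 lower, and edgeR without replicate 1 labelled WT called ID1 and 1 gene of epithelial to mesenchymal transition higher. Without replicate 2 labelled WT, edgeR called 2 higher and 2 lower BMP target genes, 2 and 1 of the integrated stress response, 3 higher of the cell cycle, 2 higher of immediate early and heat shock, 1 higher each of fibroblast and tricarboxylic acid cycle, 2 lower each of mesoderm, epithelial to mesenchymal transition and imprinted genes, and 1 lower p53 target. The median differed in sign from the mean for p53 targets (mean 0.082), BMP targets (-0.024), endothelial and blood (0.054) and immediate early and heat shock (-0.019). Without replicate 1 labelled WT the p53 list was called higher (median 0.21). Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had a median of 0.70 over 7 tested genes (camera adjusted p = 0.0113, and adjusted p = 0.699 with an estimated correlation) and 0 calls, with 1 higher, HIST1H2AC, when adjusted over the list alone. Their median was 0.34 without replicate 1 labelled WT, where the call was lost (0.158), and 1.19 without replicate 2. Over all 31 lists, camera called 12, 7 higher and 5 lower, and 0 with an estimated correlation. Fry called 0 lists in a common direction (smallest adjusted p = 0.0872) and 4 in either direction (0.0417), the naive pluripotency, neuroectoderm, neural crest and Nodal/Activin lists.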

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

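The length and GC correction was chosen after seeing the data. Of 492 pairs of a gene list and an alternative, 456 stayed on the same side of the threshold (23 of them uncalled values that changed sign), 28 lost a call and 5 gained one in the same direction, and in 3 the median changed sign with a call in at least 1 of the 2 fits. Of 1433 pairs of a named gene and an alternative, 1348 stayed on the same side (45 of them uncalled with a changed sign), 28 lost a call, 57 gained one and 0 reversed. The 26 called named genes all kept their calls under other scalings, no filter, DESeq2, the legacy estimate, the block, mitochondrial genes left out, the length and GC correction and without either library labelled WT. Without replicate 1 labelled CPT2 KO 12 were lost and without replicate 2, 11, while limma-voom lost 3, and under the stricter filter HOXD10 and TBX3 lost theirs and NPFFR2 and SIX6 were not tested. A library left alone in its group was assumed to vary like the other group. Without either library labelled WT the spread came from the pair labelled CPT2 KO alone. Its chi-square per degree of freedom was 11.3, against 43.8 for the pair labelled WT, which favours keeping calls there. The cause of the changes below was not tested, except that a stricter threshold or test calls fewer genes by construction.

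Counts of higher and lower genes were 101 and 23 with no filter (14 at least 2-fold lower) and 149 and 46 with DESeq2 (115 and 25 at least 2-fold). They were 27 and 2 at a threshold of 0.01 and 31 and 3 against a 1.5-fold change, with the same numbers at least 2-fold. With libraries left out, higher genes ranged from 31 to 531, lower from 2 to 674, at least 2-fold higher from 31 to 230 and at least 2-fold lower from 2 to 285. The share of higher calls was 86.3% with all libraries, and no scaling moved it by over 10 points, while it was 76.4% with DESeq2 and, with libraries left out, 44.1% (without replicate 2 labelled WT) to 97.6%. The CPT2 log2 fold change ranged from 1.64 to 1.95.

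With the replicate number as a block, edgeR called 233 higher and 140 lower, 142 and 56 at least 2-fold, including all 73 calls made without it, a share of higher calls of 62.5%. The block takes up differences between replicates 1 and 2 and leaves fewer residual degrees of freedom than the 2 of the main fit. The added calls depend on it. Called members under the block were 8 higher and 1 lower in mesendoderm, 2 and 1 in naive pluripotency, 1 and 2 in neural crest and 1 and 1 in BMP targets. Higher only were 7 in Nodal/Activin, 4 in definitive endoderm, 2 in primed pluripotency and 1 each in fibroblast, Wnt targets, lipid droplet, nuclear oxidative phosphorylation and heat shock. Lower only were 2 in fatty acid synthesis, 3 in hypoxia, 5 in cholesterol, 3 in neuroectoderm and 1 each in glycolysis, mesoderm, integrated stress response and acetylation, and the other lists had 0. The primed pluripotency (median 0.10) and fatty acid synthesis lists (-0.11) gained a call under the block. The labels do not say that equal numbers pair the samples, and the differences between replicates 1 and 2 of the groups correlated at r = 0.36 across 10637 genes, which are not independent replicates.

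With an estimated correlation the 12 called lists lost their calls at unchanged medians, naive pluripotency 0.54, mesendoderm 3.52, definitive endoderm 0.51, neuroectoderm -0.32, Nodal/Activin 0.28, cholesterol -0.50, glycolysis -0.66, nuclear 0.24 and mitochondrial 0.56 oxidative phosphorylation, acetylation -0.18, hypoxia -0.94 and histones 0.70. The stricter filter ended the calls of naive pluripotency (0.17) and definitive endoderm (0.17 over 5 tested genes). With no filter the definitive endoderm median was 3.21 over 17 tested genes. Limma-voom ended the call of naive pluripotency (0.40), no filter that of histones (0.59) and the length and GC correction that of acetylation (-0.11). No filter added trophoblast and amnion (0.67), and DESeq2 added fatty acid synthesis (-0.11). With each library left out, medians ranged from 0.35 to 0.60 for naive pluripotency, 0.23 to 1.57 for definitive endoderm, 2.49 to 4.19 for mesendoderm, 0.12 to 0.27 for Nodal/Activin, -0.32 to -0.16 for neuroectoderm, 0.17 to 1.09 for mitochondrial oxidative phosphorylation, -0.22 to -0.059 for fatty acid synthesis, -0.79 to -0.036 for cholesterol, -1.17 to 0.18 for glycolysis, 0.13 to 0.34 for nuclear oxidative phosphorylation, -0.24 to -0.053 for acetylation, -0.21 to 0.21 for p53 targets, -1.56 to 0.10 for hypoxia and 0.34 to 1.19 for histones. Without replicate 1 labelled WT these medians changed sign: glycolysis (0.18) was called in both directions, hypoxia (0.10) lost its call, and p53 targets (0.21), uncalled in the main fit, gained one. The mitochondrially encoded list has no value with mitochondrial genes left out. In simulated data 10.8% of 1.5-fold changes were recovered, so changes of that size mostly went uncalled there. The share missed in the 4 libraries is not known.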

Other observations

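The tests of exchanged labels, neighbouring genes, a common mesendoderm population, genes off in a group and HOX genes were chosen after the results were seen. Of 11 tested HOX genes, which set position along the body axis, 10 had a negative log2 fold change in the libraries labelled CPT2 KO and 1 a positive one, with a median of -0.99. HOXD10 and HOXC4 were called, and HOXD9 and HOXB3 had values of -2.55 and -0.99 (edgeR adjusted p = 0.110 and 0.168). Camera gave p = 5.4e-10 (2.1e-09 adjusted over the 4 gene families tried) and p = 0.0228 with an estimated correlation (0.0911 adjusted), so the shift of the class passed with the preset correlation alone after adjustment. The HOX median stayed between -1.27 and -0.94 under the other scalings, the length and GC correction and each library left out. The other families, metallothioneins, clustered protocadherins and ZNF genes, were not called (limma camera adjusted p = 0.593, 0.496 and 0.955), and the metallothionein median of -1.21 was opposite in sign to its test. No autosome had a median beyond 0.0348 in size, while the largest median of a 10 Mb window was 0.28 (SE 0.19, chromosome 18), so a copy number difference of a region could not be excluded.

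CPT2 was higher, not lower, in the libraries labelled CPT2 KO. Scaling of the libraries is argued against, since the lowest log2 fold change over the scalings was 1.76. A change of the whole region is argued against too, since 25 tested genes within 1 Mb had a median log2 fold change of 0.026 (SE 0.082). That median cannot show a change limited to CPT2 or reads from 1 overlapping gene. The overlapping gene CZIB, not among the 25, did not rise (log2 fold change -0.12), and AL606760.2 had 0 counts in both libraries labelled CPT2 KO. Exchanged labels of the groups cannot be told apart from a CPT2 transcript that is raised in edited cells: 100% of the 4 genes off in a group (at most 3 counts per library, and at least 5 CPM in the other) were off in the libraries labelled WT, but the labels name no clone and no edited position, and a disrupted gene may keep its transcript. Equal numbers in both directions could not be tested on 4 genes (exact binomial p = 0.125, two-sided, the smallest they can give). At a limit of 1 CPM, added later, 24 of 27 genes were off in the libraries labelled WT (exact binomial p = 4.9e-05). Y-linked genes and XIST were left out at 5 CPM but not at 1 CPM. That p takes genes as independent, which is doubtful: CER1, GATA6 (74 and 7 counts) and SOX17 (46 and 7) were all much higher in replicate 1 than 2 labelled CPT2 KO.

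NODAL, LEFTY1 and LEFTY2 were higher in both libraries labelled CPT2 KO. For these 3 genes a single library as the source is argued against by their values in the 2 libraries labelled CPT2 KO. NODAL stood at 43.7 and 31.8 CPM, LEFTY1 at 9.06 and 9.28 and LEFTY2 at 10.9 and 9.70. All 3 also kept their calls without replicate 1, but they were picked as called with both libraries, which favours that outcome. For a common population of mesendoderm cells, the log2 ratios of replicate 1 to 2 of these genes and of the 11 other tested mesendoderm markers differed by -1.50 (exact permutation p = 0.0632, two-sided), but this decides nothing: the Nodal genes were picked because they were called, which favours agreement between replicates, and the called markers FGF8 (0.30) and WNT3 (0.61) had ratios near theirs (-0.034 to 0.46). The p also changed side of 0.05 with the genes compared: it was under 0.05 with a further called Nodal gene, taken out after that result was known because it is not reported here, and 0.0091 with a narrower set of 9 markers, tried first and not kept. A common population, populations at different stages and a genotype effect stay open.

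The 6 metabolic and stress lists shifted together. Without replicate 1 of the group labelled WT, 2 of 6 lists (both of oxidative phosphorylation) kept call and direction. That count does not single out the library: hypoxia, glycolysis, acetylation and nuclear oxidative phosphorylation also lost calls without replicate 2 labelled CPT2 KO. The lists were also picked as called with all 4 libraries, which favours losses. The medians of hypoxia and glycolysis turned positive (0.10 and 0.18) only without replicate 1 labelled WT. They were -0.66 and -0.53 without replicate 2 labelled CPT2 KO. For these 2 lists the values go with a single library labelled WT standing apart. Gene length and GC content cannot be excluded for all lists: 5 of 6 kept call and direction with the trend removed, and acetylation went from -0.18 to -0.11 (camera adjusted p = 0.0113 to 0.0805), its median being smaller after correction. Replicate 1 minus replicate 2 had a median log2 difference of 1.73 labelled WT and 0.65 labelled CPT2 KO for hypoxia, 1.29 and 0.18 for glycolysis, and 0.64 and 0.21 for cholesterol. The values were 0.11 and 0.083 for acetylation, and -0.19 and -0.24 for nuclear and -0.92 and 0.064 for mitochondrial oxidative phosphorylation. A difference between replicate numbers shared by the groups stays open too for the lists with the same sign in both groups. For glycolysis it was much smaller labelled CPT2 KO, and the mitochondrially encoded values differed in sign. Why replicate 1 labelled WT differed was not tested, and an effect of the genotype on oxidative phosphorylation stays open.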
